A study of Mus musculus with 12 samples.

How the data were processed

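RNA of 12 libraries of mouse CD8 T cells in 4 groups of 3 was sequenced as paired reads of 150 bases, and per the labels the libraries were made with a stranded total RNA kit with removal of ribosomal RNA. Per the labels, bcl2fastq, cutadapt 1.18, STAR 2.7.0f and RSEM 1.3.1 were used with the mm10 genome, without a role being given for each tool. The authors deposited 1 gene table per library, and per the file headers these hold expected counts, TPM, FPKM and effective lengths. Each table lists 55450 genes, and all IDs and symbols equal those of GENCODE mouse release 21, which supplied the coordinates on mm10. Expected counts, as deposited, were rounded for the tests, and the deposited TPM served only for the levels of single genes named with that unit. CPM were computed from the expected counts and the scaled library totals.

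Groups came from the labels. Library totals of 20838894 to 31098648 expected counts give a counting limit of 3 counts where a gene has none. Genes with low counts were removed with the filterByExpr function of edgeR 4.0.16 under R 4.3.3, which left 13636 genes. TMM normalization factors ran from 0.961 to 1.05. A negative binomial model with 1 mean per group was fitted to all 12 libraries, with 8 residual degrees of freedom and 12.6 prior degrees of freedom, and contrasts were tested with the quasi-likelihood F test. Adjusted p values follow Benjamini and Hochberg, and a gene was called at adjusted p under 0.05. The 6 contrasts were genipin against vehicle, NAC against vehicle, both compounds against each of the other 3 groups, and the interaction. The interaction is the genipin effect with NAC minus that without it. Standard errors (SE) were derived as the absolute log2 fold change divided by the square root of the F statistic. They can be too small where a group has few counts.

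In all, 40 gene lists with 690 members, 626 of them tested, were fixed before the data were examined. So were the contrasts, the tests of genes and lists, the naming rule and all but 1 of the other settings tried. Some tests of explanations were chosen after the result was seen and are named with those results. Lists were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, which compares a list with all other genes, and again with the correlation estimated from the data. The fry test asks whether the genes of a list move on balance in 1 direction, its mixed form asks for change in either direction, and neither compares the list with other genes. Member counts are given from the adjustment over all genes and from an adjustment over the list alone.

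The naming rule took Ucp2 first. For each contrast it then took genes with adjusted p under 0.05, a mean of at least 5 CPM in the libraries compared and no overlap between the groups (a condition left out for the interaction), without predicted genes and pseudogenes. The 10 largest rises and 10 largest falls were eligible, or 5 and 5 for the interaction and for both compounds against vehicle or NAC. From each list, up to 4 members with the smallest p were eligible, or up to 2 where none passed. Ucp1 to Ucp3 completed the rule, and the text describes a part of the genes it names. Single results of some genes are not reported here, and those genes stay in the tests, counts and lists.

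The steps were tested on simulated data with known changes. With 50 genes changed at each size over 13636 genes, genipin against vehicle recovered 23, 29, 46 and 46 of 50 at log2 changes of 0.25, 0.5, 1 and 2, with 12 false calls (7.69% of calls). The interaction recovered 12, 23, 44 and 43 of 50, with 10 false calls (7.58%). Camera called the list that was moved and none of the others. The simulated genes were drawn independently, so this does not show how camera behaves on lists of correlated genes. Relations between contrasts that share libraries were also simulated 10 times without group differences.

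Results were recomputed with RLE size factors, no normalization factors, DESeq2 1.42.0, limma-voom, no filter, a filter at a mean of 5 CPM, an adjusted p under 0.01, a change of at least 2-fold, only the groups compared, offsets from effective lengths, abundant RNAs left out, the replicate number as a block, each library left out in turn, and fry or an estimated correlation for lists. A glmTreat test against a 1.5-fold change was added after seeing the data, because most genes passed. Replicate numbers were checked for pairing: libraries with the same number correlated between -0.0751 and 0.0437 over 18 pairs once group means were removed, and 4 of 12 libraries correlated best with their own number. These values gave no sign of pairing and the model has none, but the labels do not say how the replicates were set up. FPKM values, which the authors deposited beside TPM, were left out because they repeat the same counts. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.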

Results

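The labels describe total RNA from CD8 T cells of pmel-1 mice, whose transgenic T cell receptor recognises a peptide of the melanoma antigen gp100. The cells had the wild-type Ucp2 gene, were activated through their receptor and grew for 4 days in IL-2 at 10 ng/ml. The labels allow 2 routes of activation, the peptide or antibodies to CD3 and CD28, and do not say which one these libraries had. The 12 libraries formed 4 groups of 3: vehicle (culture medium), genipin, genipin with N-acetylcysteine (NAC), and NAC alone. Genipin is a plant compound used to inhibit the mitochondrial carrier protein Ucp2, and NAC is a thiol antioxidant that supplies cysteine. Library totals ran from 20838894 to 31098648 expected counts, and 13636 genes passed the filter on low counts. The labels give no doses and do not say whether the replicates of a group came from separate mice or cultures. The p-values therefore measure only the spread between these libraries, which was small: the common biological coefficient of variation was 0.0393.

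The 4 groups separated without overlap in a principal component analysis. The first component held 55.5% of the variance and ran from the genipin libraries, near -63, to the NAC libraries, near 49. The vehicle libraries lay near -10 and the libraries with both compounds between 24.0 and 24.9. The lowest correlation between replicates of a group across genes was 0.990. In the group with both compounds, replicate 1 stood apart from the others: its chi-square per degree of freedom was 7.23 against replicate 2 and 8.29 against replicate 3, while replicates 2 and 3 gave 2.09. The pairs of the other groups lay between 2.23 and 3.01.

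**Figure D1:**
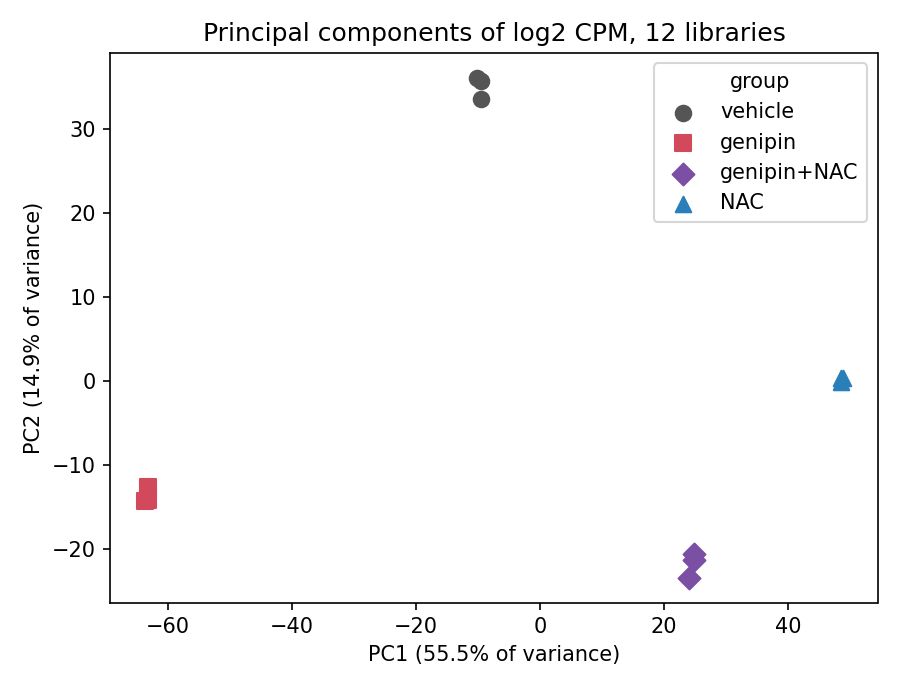
Principal components of log2 CPM (counts scaled to library totals) in the 12 libraries, with component 1 on the x axis (55.5% of the variance) and component 2 on the y axis (14.9%). Each point is 1 library, and the 3 libraries of each group lie together and apart from the other groups.

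Ucp2, the mitochondrial uncoupling carrier named in the title of the series (ENSMUSG00000033685.13, chromosome 7, 100493337 to 100502020, mm10), was abundant in every library. Its TPM values (length-scaled transcript abundance) were 695, 664 and 668 with vehicle, 591, 598 and 621 with genipin, 505, 529 and 523 with both compounds, and 488, 513 and 500 with NAC. Relative to vehicle, its log2 fold change ± SE was -0.27 ± 0.03 with genipin, -0.64 ± 0.03 with NAC and -0.47 ± 0.03 with both. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 6.02e-07, 1.23e-12 and 1.75e-10 for these 3 differences. Genipin acts on the protein, so these transcript levels do not measure its inhibition. Ucp1 had 0 counts in all 12 libraries, which allows up to 3 counts in each, between 0.0965 and 0.144 CPM, for counting error only. Ucp3 had 1 to 13 counts per library, and neither gene was tested. Of the adenine nucleotide carriers, Slc25a4 fell against vehicle with genipin (-0.39 ± 0.03), NAC (-0.49 ± 0.03) and both (-0.32 ± 0.03), and Slc25a5 fell with NAC (-0.51 ± 0.03) and both (-0.68 ± 0.03).

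The first comparison, genipin against vehicle, asks what the compound described as a Ucp2 inhibitor changed without NAC. Values in parentheses here and in the later comparisons are log2 fold changes ± SE with n = 3 libraries per group. Genipin lowered the transcripts of lipid synthesis, glycolysis and the hypoxia response together, and raised those of the cell cycle. The glycolytic kinase gene Pgk1 (ENSMUSG00000062070.12, chromosome X, 106187100 to 106203699) fell from 3472 ± 71.2 CPM (SD, n = 3) to 910 ± 1.92 CPM (-1.93 ± 0.02). Acat2, which condenses acetyl-CoA at the start of the sterol pathway (ENSMUSG00000023832.14, chromosome 17, 12942890 to 12960747), fell from 143 ± 2.29 to 32.4 ± 0.613 CPM (-2.14 ± 0.04). The proliferation marker Mki67 (ENSMUSG00000031004.8, chromosome 7, 135689784 to 135716361) rose from 318 ± 4.84 to 747 ± 15.5 CPM (1.23 ± 0.04). In the 20 genes with the largest changes by the naming rule, genipin raised Itgae (3.93 ± 0.16), the CD103 integrin chain that binds E-cadherin, and the calmodulin-binding Nrgn (3.59 ± 0.08). It also raised Asb2 (3.43 ± 0.11), a substrate receptor of ubiquitin ligases, the Ly49 family receptor Klra5 (3.17 ± 0.11), the protease inhibitor Serpina3g (2.98 ± 0.07) and the macrophage growth factor Csf1 (2.703 ± 0.14). The NADPH-forming malic enzyme Me1 (-3.31 ± 0.11), the lipoprotein receptor Lrp1 (-3.34 ± 0.12), the hypoxia-induced mitochondrial protein Mgarp (-3.15 ± 0.12) and the cytokine Lif (-2.76 ± 0.04) fell.

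Among the lists fixed beforehand, cholesterol synthesis fell most evenly with genipin: 22 of 23 measured members fell and none rose, with a median of -1.13. Fdps (-1.78 ± 0.03), Fdft1 (-1.75 ± 0.04) and Hmgcs1 (-1.49 ± 0.03), all enzymes of the mevalonate and sterol route, were among them. Of 13 fatty acid synthesis genes 11 fell, including the desaturase Scd1 (-1.99 ± 0.04) and the acyl-CoA synthetase Acsl3 (-2.34 ± 0.09), and the median was -0.56. Of 17 targets of the hypoxia-inducible factor (HIF), 16 fell and 1 rose, with a median of -0.998. The mitophagy receptor Bnip3 (-1.71 ± 0.04), the oxygen-sensing hydroxylase Egln3 (-1.67 ± 0.04) and the angiogenic factor Vegfa (-2.45 ± 0.06) stood for this list. Of 19 glycolysis genes 18 fell, with Aldoc at -2.49 ± 0.05 and Aldoa at -1.46 ± 0.04, and the median was -0.59. Each of these counts was the same when adjusted over the list alone. The camera test, which asks whether a list moved more than the other genes, gave adjusted p = 4.67e-62 for cholesterol synthesis, 1.91e-15 for fatty acid synthesis, 3.07e-29 for HIF targets and 5.95e-34 for glycolysis. With an estimated correlation the adjusted p values were 2.76e-06, 0.000249, 3.42e-05 and 0.00149.

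Stress and signalling lists also fell with genipin. Of 26 genes of the integrated stress response 22 fell and 1 rose, including the glutathione-degrading enzyme Chac1 (-2.73 ± 0.11), Atf3 (-1.68 ± 0.06), Ddit4 (-1.51 ± 0.04) and the asparagine synthetase Asns (-1.01 ± 0.03), with a median of -0.59. Of 20 p53 targets 18 fell and 1 rose, among them Btg2 (-1.44 ± 0.04), an antiproliferative factor, and the cell cycle inhibitor Cdkn1a (-0.78 ± 0.03). Of 16 immediate early genes 13 fell and none rose, with the transcription factor Egr1 at -1.69 ± 0.03 and the phosphatase Dusp5 at -1.20 ± 0.03. These counts did not change when adjusted over the list alone. For the stress response, p53 and immediate early lists camera gave adjusted p = 8.28e-17, 5.62e-08 and 3.74e-16, and 0.00693, 0.00149 and 0.00442 with an estimated correlation.

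Cell cycle transcripts moved the other way. All 22 mitosis genes rose, with a median of 0.64, and 20 of 22 replication genes rose, with a median of 0.53. The mitotic kinesin Kif20a (1.08 ± 0.04), the cyclin Ccna2 (0.83 ± 0.04), the thymidylate synthase Tyms (1.00 ± 0.05) and the ribonucleotide reductase subunit Rrm2 (0.76 ± 0.03) were examples. The counts were the same adjusted over the list alone, and camera gave adjusted p = 1.30e-24 for mitosis and 3.77e-13 for replication, or 0.00011 and 0.00149 with an estimated correlation. Of 13 mitochondrially encoded respiratory genes 12 rose, led by mt-Cytb (0.89 ± 0.04), with a camera adjusted p of 0.000202 that was lost at adjusted p = 0.164 with an estimated correlation. The unfolded protein response list of the endoplasmic reticulum had 12 of 18 members higher and 1 lower, 13 and 2 adjusted over the list alone, including Calr (0.44 ± 0.03), and a camera adjusted p of 0.00118, but adjusted p = 0.0531 with an estimated correlation.

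T cell genes were divided after genipin. The naive and memory list fell, with 10 of 19 members lower (11 adjusted over the list alone) and 4 higher: the lymph node homing receptor Ccr7 went from 110 ± 2.61 to 18.8 ± 1.55 CPM (-2.56 ± 0.05), and the egress receptor S1pr1 (-2.37 ± 0.06) and the IL-7 receptor Il7r (-1.13 ± 0.04) fell as well. For this list camera gave adjusted p = 7.73e-05, or 0.00693 with an estimated correlation. Of the effector list 14 of 26 members rose, with Gzma at 0.77 ± 0.03, and 8 fell, with the IL-2 receptor chain Il2ra at -0.83 ± 0.03 and the transcription factor Irf4 at -1.04 ± 0.03. That list had no net call (camera adjusted p = 0.227). Members of the exhaustion list were split, 10 higher and 8 lower, without a call (camera adjusted p = 0.341). Cd160 rose by 2.55 ± 0.07 while the costimulatory Tnfrsf9 (-1.50 ± 0.03) and the inhibitory Ctla4 (-1.56 ± 0.04) fell. The chemokines Ccl5 (1.29 ± 0.03) and Ccl4 (1.32 ± 0.06) rose. Among markers of natural killer cells 5 of 6 rose, including the signalling adaptor Fcer1g (1.24 ± 0.05) and the receptor Klrb1c (1.44 ± 0.15), with adjusted p = 0.000154 by camera and 0.0110 with an estimated correlation. Of 12 neutrophil and mast cell markers 3 were tested (Kit, Cpa3 and Mcpt8), and the others had at most 15 counts in any library. All 3 rose, with a median of 1.15 (camera adjusted p = 0.00212, or 0.0272 with an estimated correlation).

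By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment under 0.05, 8312 genes differed between genipin and vehicle, 4080 higher and 4232 lower, and without normalization factors 4871 higher and 3550 lower. With a change of at least 2-fold as well, 1336 remained, 424 higher and 912 lower, so the larger changes were mostly falls. Across the 40 lists camera called 7 up and 13 down, and 15 of these 20 calls were kept with an estimated correlation. Besides the 2 named above, the lost calls were other antioxidant enzymes (adjusted p = 0.192 with an estimated correlation), heat shock genes (0.165) and dendritic cell markers (0.118), all called down.

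**Figure D2:**
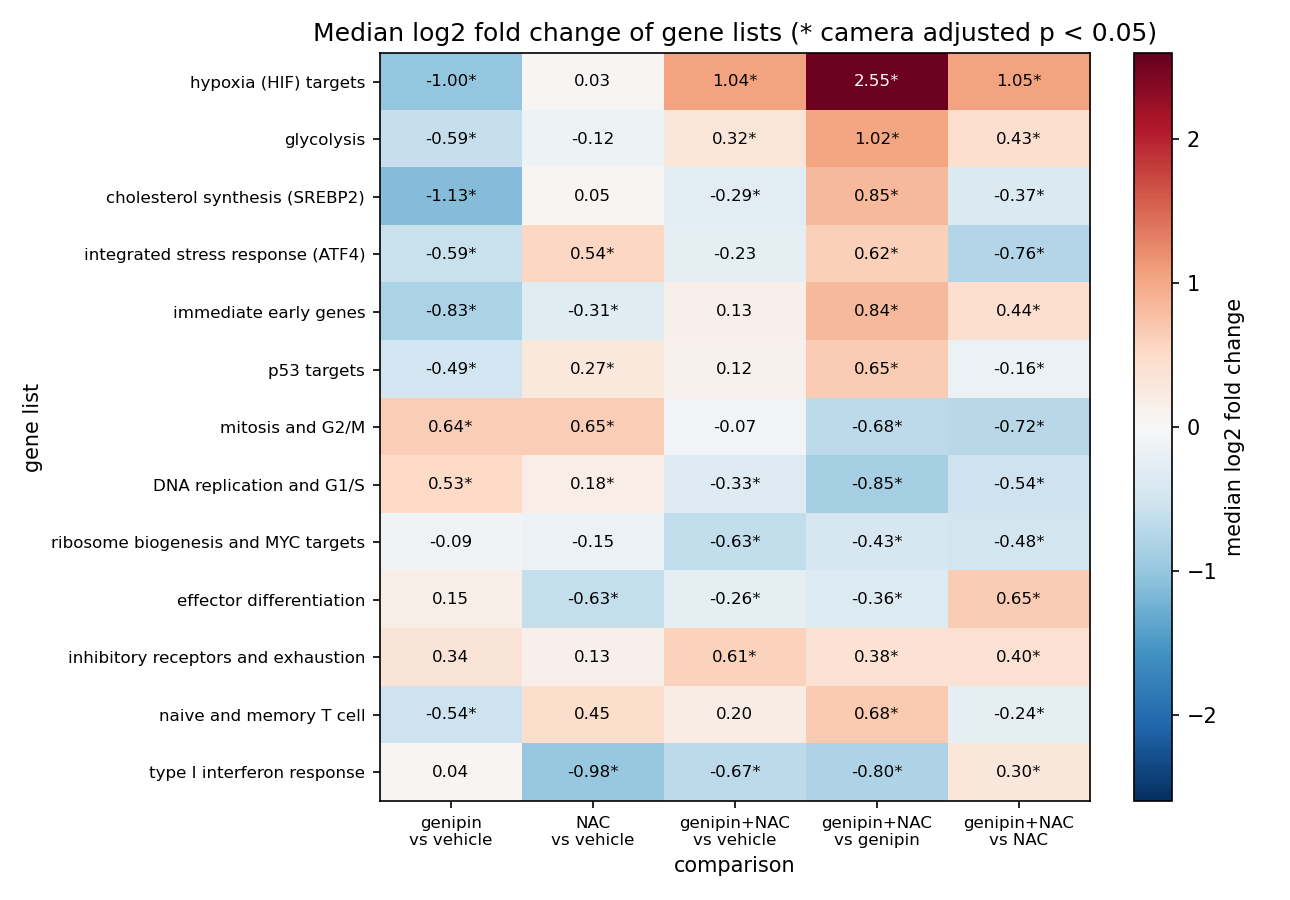
Median log2 fold change (colour and printed value) of 13 gene lists (y axis) in 5 comparisons (x axis), with an asterisk where the camera adjusted p was under 0.05 at the preset correlation. HIF targets had a median of -0.998 with genipin against vehicle, 0.03 with NAC against vehicle and 2.55 when NAC was added to genipin.

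NAC against vehicle asks what the antioxidant changed without genipin. The NAC libraries had lower levels of most effector and interferon-response list genes and of the chemokines Ccl4, Ccl5 and Ccl9, and more Tcf7. Gzma, a granzyme of cytotoxic granules (ENSMUSG00000023132.8, chromosome 13, 113093825 to 113100981), fell from 965 ± 25.3 to 122.9 ± 1.76 CPM (-2.97 ± 0.03). Tcf7, the transcription factor TCF-1 of naive and memory T cells (ENSMUSG00000000782.15, chromosome 11, 52252371 to 52283014), rose from 6.61 ± 0.898 to 88.1 ± 3.28 CPM (3.73 ± 0.08). The chemokine receptor Ccr2 (ENSMUSG00000049103.14, chromosome 9, 124101950 to 124113557) fell from 234 ± 3.01 to 24.8 ± 0.781 CPM (-3.23 ± 0.04). The chemokine Ccl9 fell from 12.2 ± 0.696 CPM to 0.0533 ± 0.0202 CPM (-7.71 ± 0.26). Its mean with NAC lay below the level of 3 counts per library, so the size of this fall is uncertain. The terminal effector marker Klrg1 (-3.05 ± 0.14), the cell cycle inhibitor locus Cdkn2a (-3.42 ± 0.07), the chemokine receptor Ccr1 (-3.16 ± 0.07), the protease inhibitor Serpinb9b (-3.66 ± 0.08) and the activation-induced Egr3 (-3.37 ± 0.10) fell too. Nsg2 (3.79 ± 0.12), Itgae (3.63 ± 0.16), the inducible chaperone Hspa1a (3.53 ± 0.21), the tetraspanin Cd9 (3.04 ± 0.14) and Pld4 (3.23 ± 0.16) rose.

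The effector list fell with NAC in 21 of 26 members and rose in 2, with a median of -0.63. Gzmc (-2.38 ± 0.03), Gzmf (-2.63 ± 0.03) and Gzmg (-2.90 ± 0.03) fell along with Gzma. Of 22 interferon-response genes 19 fell and 2 rose, with a median of -0.98: the antiviral GTPase Mx1 (-2.09 ± 0.05), the ubiquitin-like Isg15 (-2.13 ± 0.08) and the transcription factor Irf7 (-2.09 ± 0.06) were examples. Of 15 cytokine and chemokine genes 8 fell and 6 rose, and the falls were larger: Ccl5 fell by 2.61 ± 0.04, Ccl4 by 2.47 ± 0.08, Il10 by 2.92 ± 0.09 and Spp1 by 1.42 ± 0.04 on the log2 scale. The counts were the same adjusted over the list alone, and camera gave adjusted p = 3.65e-74, 3.95e-15 and 1.62e-08 for the 3 lists. With an estimated correlation these became 1.78e-05, 0.000369 and 0.00208. Among cytokine and chemokine receptors 10 of 22 fell, among them Cxcr6 (-2.41 ± 0.05), and 8 rose (9 adjusted over the list alone). Their median of -0.09 became 0.03 without normalization factors, while camera called the list down with adjusted p = 1.76e-06, or 0.00393 with an estimated correlation.

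The naive and memory list had 12 of 19 members higher and 5 lower with NAC, both counts unchanged adjusted over the list alone. Bcl2, which protects from apoptosis, rose by 0.74 ± 0.03. The list was not called (camera adjusted p = 0.0537). The CD8 T cell identity list was split, 7 higher and 7 lower of 16 (the same adjusted over the list alone), with Cd8a at 0.80 ± 0.03, Cd8b1 at 0.55 ± 0.03 and Thy1 at -0.40 ± 0.03, and was not called (camera adjusted p = 0.328). The early T cell receptor response gene Nr4a1 rose (2.24 ± 0.08) while the inhibitory receptor Havcr2 (-1.27 ± 0.04) and the receptor Cd244a (-1.24 ± 0.05) fell, and the exhaustion list had no call (camera adjusted p = 0.973), with a median of 0.13 and a mean of 0.43 while the test pointed down. Natural killer markers fell in 5 of 6 cases, with Fcer1g at -2.45 ± 0.07, and camera gave adjusted p = 0.00153, or 0.0304 with an estimated correlation. Of 11 B cell markers 5 were tested, 3 of them higher and none lower, with Ighm at 2.26 ± 0.04 and Cd79b at 1.88 ± 0.16. The B cell list was called up (camera adjusted p = 7.14e-07, or 0.00419 with an estimated correlation).

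Mitosis and integrated stress response genes rose with NAC. All 22 mitosis genes were higher, with a median of 0.65 and examples such as Cdc20 (0.81 ± 0.04), an activator of the anaphase-promoting complex, and Ube2c (0.80 ± 0.03). Of 22 replication genes 13 rose and 3 fell. Of 26 integrated stress response genes 22 rose and 1 fell, including the pseudokinase Trib3 (1.73 ± 0.06), Atf5 (1.71 ± 0.08) and Asns (0.76 ± 0.03), with a median of 0.54. These counts held adjusted over the list alone. By camera, adjusted p was 1.78e-20 for mitosis, 1.66e-12 for the stress response and 0.0414 for replication. With an estimated correlation the values were 0.000369 and 0.0176, and the replication call was lost at adjusted p = 0.180 with an estimated correlation. It was also lost without vehicle replicate 1 (adjusted p = 0.0548) or without NAC replicate 1 (adjusted p = 0.0559). Of 20 p53 targets 13 rose (14 adjusted over the list alone) and 2 fell, with the death receptor Fas at 1.24 ± 0.07 and a camera adjusted p of 0.0108, or 0.0480 with an estimated correlation. The heat shock and unfolded protein response lists had no call (camera adjusted p = 0.973 and 0.313).

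The metallothioneins, which bind zinc and copper, were lower in NAC libraries: Mt2 fell from 235 ± 10.2 to 37.6 ± 1.78 CPM (-2.65 ± 0.04) and Mt1 fell by 2.01 ± 0.06. The metallothionein and zinc transport list had 9 of 16 members lower and 3 higher, both also adjusted over the list alone (camera adjusted p = 0.000334, or 0.0167 with an estimated correlation). Of 22 NRF2 antioxidant genes 13 fell and 3 rose, adjusted over the list alone too, with the sulfiredoxin Srxn1 at -0.997 ± 0.07 and the peroxiredoxin Prdx1 at -0.43 ± 0.03. Its camera adjusted p of 0.0118 was lost, at adjusted p = 0.186 with an estimated correlation. Other antioxidant enzymes, 5 higher and 6 lower of 16, had no call (camera adjusted p = 0.222). Of 30 nuclear genes of oxidative phosphorylation 25 fell, the same number adjusted over the list alone, by a median of -0.22, with a camera adjusted p of 0.000142 that was lost at adjusted p = 0.0706 with an estimated correlation. HIF targets were divided, 7 higher and 5 lower of 17, with no call (camera adjusted p = 0.853).

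In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 8134 genes between NAC and vehicle, 4041 higher and 4093 lower, and 1352 of them changed at least 2-fold, 823 higher and 529 lower. Without normalization factors the split was 5615 higher and 2700 lower, since that scaling shifts the median of all genes by 0.11 on the log2 scale. The directions above are those relative to TMM scaling. Camera called 6 lists up and 12 down, and 12 of the 18 were kept with an estimated correlation. The lost calls not named above were immediate early genes (adjusted p = 0.107 with an estimated correlation) and mitochondrially encoded respiratory genes (0.228), both called down, and markers of CD4 and regulatory T cells (0.115), called up.

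**Figure D3:**
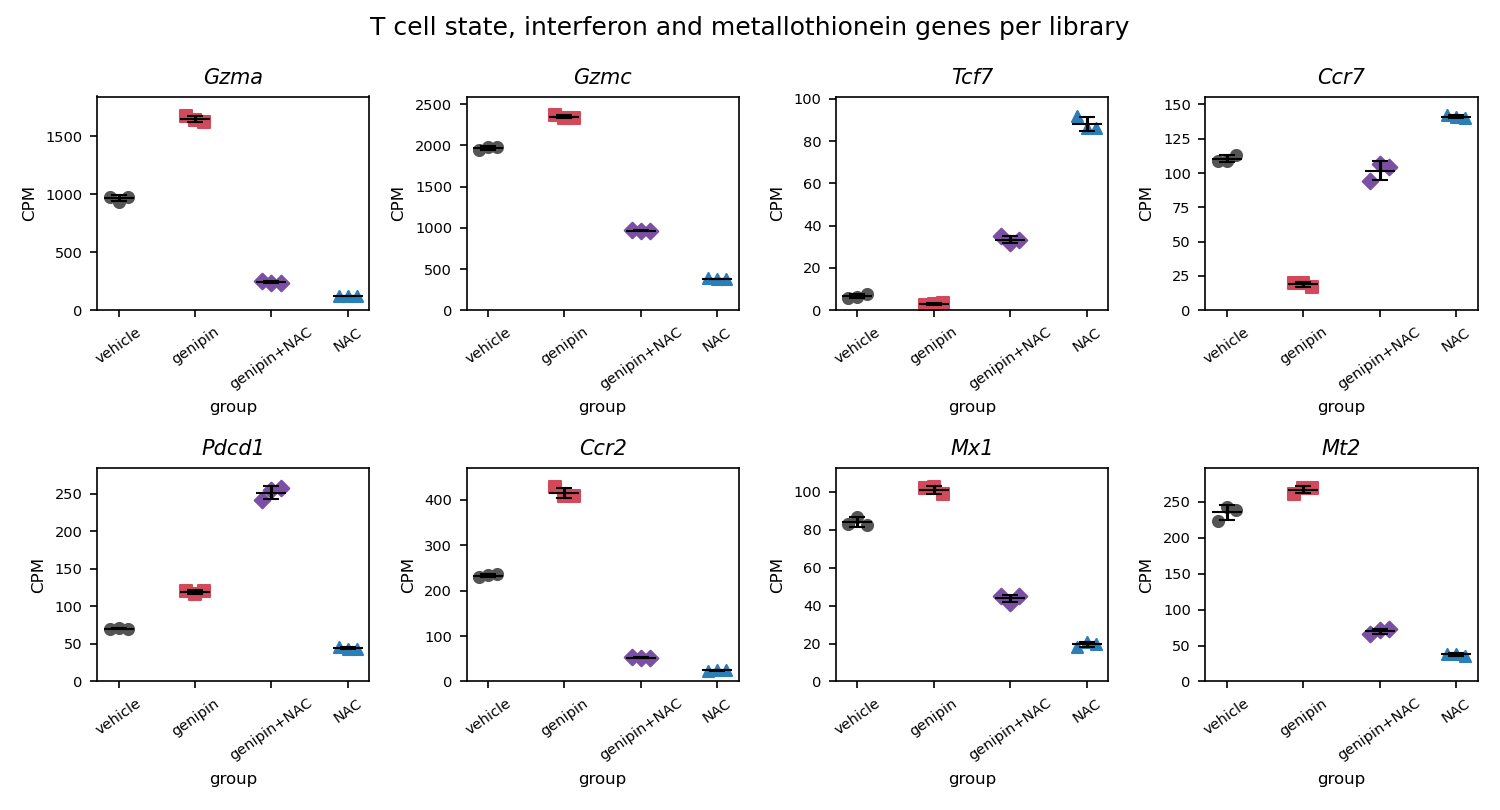
CPM (y axis, from 0) of 8 T cell state, interferon and metallothionein genes in each library of the 4 groups (x axis), with the mean and SD of 3 libraries as black bars. Gzma averaged 965 CPM with vehicle, 1650 with genipin, 243 with both compounds and 122.9 with NAC.

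Both compounds against vehicle asks how the combination left the cells relative to untreated ones. HIF targets and glycolysis genes were above vehicle, the reverse of genipin alone. The stem cell factor receptor Kit (ENSMUSG00000005672.12, chromosome 5, 75574916 to 75656722) rose from 15.3 ± 0.809 to 237 ± 2.52 CPM (3.95 ± 0.04). The inhibitory receptor gene Pdcd1, which encodes PD-1 (ENSMUSG00000026285.7, chromosome 1, 94038305 to 94052553), rose from 70.5 ± 1.21 to 252 ± 8.79 CPM (1.84 ± 0.03). Cd9 (3.53 ± 0.14) and the sialyltransferase St6gal1 (3.08 ± 0.15) also rose, and Ccl9 (-5.76 ± 0.21), Ermn (-5.16 ± 0.22) and Cdkn2a (-2.84 ± 0.07) fell.

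All 17 HIF targets rose against vehicle, with a median of 1.04, including Egln3 (1.66 ± 0.03), the stress-induced Ndrg1 (1.56 ± 0.03) and the oxidoreductase of the endoplasmic reticulum Ero1l (1.55 ± 0.04). Of 19 glycolysis genes 17 rose and 1 fell, with the glucose transporter Slc2a3 at 1.74 ± 0.03 and the lactate exporter Slc16a3 at 1.053 ± 0.04. Of 18 genes of the exhaustion list 15 rose and 1 fell, among them Pdcd1, Lag3 (0.69 ± 0.04), Ctla4 (0.67 ± 0.04) and Tnfrsf9 (0.70 ± 0.03). The CD8 T cell identity list had 12 of 16 members higher and none lower, with Cd3g at 0.50 ± 0.03. The counts were the same adjusted over the list alone. Camera gave adjusted p = 3.07e-44, 1.97e-15, 1.02e-13 and 2.15e-06 for these 4 lists, and 1.28e-05, 0.00987, 0.000601 and 0.00870 with an estimated correlation.

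Growth and effector lists lay below vehicle. All 21 genes of ribosome biogenesis and MYC targets fell, with a median of -0.63, including the nucleolar proteins Nolc1 (-0.99 ± 0.03) and Nop56 (-0.95 ± 0.03). Of 22 replication genes 21 fell and 1 rose, with the cyclin Ccne1 at -0.71 ± 0.05. The effector list had 17 of 26 members lower and 5 higher (6 adjusted over the list alone), with Gzma at -1.99 ± 0.03 and Gzmc at -1.03 ± 0.02. Interferon-response genes fell in 18 of 22 cases and rose in 3, with Usp18, a brake on interferon signalling, at -2.21 ± 0.07. Cholesterol synthesis had 19 of 23 members lower and none higher (1 adjusted over the list alone), by a median of -0.29. By camera, adjusted p was 8.96e-22 for ribosome biogenesis, 2.64e-06 for replication, 1.02e-13 for effector genes, 4.58e-09 for the interferon response and 1.40e-06 for cholesterol synthesis. All 5 held with an estimated correlation, at adjusted p between 9.17e-05 and 0.00824. Mitosis genes were split, 4 higher and 10 lower of 22 (camera adjusted p = 0.452). The heat shock list was called down (adjusted p = 0.000668, or 0.0456 with an estimated correlation) with 12 of 18 members lower and 5 higher, and its median of -0.34 and mean of 0.17 differed in sign.

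The quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment called 7826 genes, 3891 higher and 3935 lower, and 1083 of them changed at least 2-fold, 733 higher and 350 lower. The split was 4400 higher and 3456 lower without normalization factors. Camera called 9 lists up and 14 down, 21 of them kept with an estimated correlation. The 2 lost were NRF2 antioxidant genes (adjusted p = 0.159 with an estimated correlation) and CD4 and regulatory T cell markers (0.167). Markers of other cell types moved in this comparison. Of 13 monocyte and macrophage markers 4 were tested, and all 4 rose, with the integrin chain Itgam at 2.23 ± 0.08 and Cd68 at 1.03 ± 0.07. Cd14 rose by 0.49 ± 0.20, a call that was lost in several other settings, such as DESeq2 (adjusted p = 0.0902) and no filter (0.0748). The list was called up (camera adjusted p = 5.36e-05, or 0.00870 with an estimated correlation). Ighm, the immunoglobulin heavy chain gene of the B cell list, was 153 ± 1.36 CPM against 39.3 ± 0.797 CPM with vehicle (1.96 ± 0.04).

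Both compounds against genipin asks what NAC changed in cells that also had genipin, and it gave the largest number of calls of the 6 comparisons. The transglutaminase Tgm2 (ENSMUSG00000037820.15, chromosome 2, 158116402 to 158146436) rose from 0.0895 ± 0.125 to 29.3 ± 1.02 CPM (8.23 ± 0.20). Its mean with genipin lay below the level of 3 counts per library, so the size of this rise is uncertain. Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826.8, chromosome 11, 78920787 to 78960254), rose from 0.542 ± 0.0352 to 22.1 ± 2.10 CPM (5.34 ± 0.14). St6gal1 (5.94 ± 0.22), Plcxd1 (5.44 ± 0.17), the adenylyl cyclase Adcy6 (4.52 ± 0.15), the class II antigen presentation gene H2-Eb1 (4.51 ± 0.16) and the collagen prolyl hydroxylase P4ha2 (4.35 ± 0.10) rose as well. Csf1 (-4.12 ± 0.17), Klra5 (-3.92 ± 0.12), Dsc2 (-3.37 ± 0.09), Nrgn (-3.07 ± 0.08), Ccr2 (-2.99 ± 0.03), Gzma (-2.77 ± 0.03) and Fcer1g (-2.47 ± 0.06) fell. Pagr1a fell by 4.27 ± 0.86 with a wide error.

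All 17 HIF targets rose when NAC was added to genipin, with a median of 2.55: Egln3 went from 45.4 ± 2.76 to 455 ± 6.93 CPM (3.32 ± 0.04), and Ero1l (3.03 ± 0.04), Bnip3 (2.75 ± 0.04) and Ndrg1 (2.55 ± 0.03) followed. Of 19 glycolysis genes 18 rose and 1 fell, with a median of 1.02, led by Aldoc (3.14 ± 0.05), Pgk1 (2.12 ± 0.02) and Slc2a3 (2.08 ± 0.03). Cholesterol synthesis rose in 21 of 23 members (22 adjusted over the list alone) and fell in 1, with Fdps at 1.503 ± 0.03 and the SREBP regulator Insig1 at 1.181 ± 0.03. Immediate early genes rose in 13 of 16 cases and fell in 1, with Egr1 at 1.82 ± 0.03, and p53 targets rose in 15 of 20 and fell in 4, with Btg2 at 2.19 ± 0.04. The other 4 lists had the same counts adjusted over the list alone. Adjusted p by camera was 2.81e-72 for HIF targets, 3.65e-51 for glycolysis, 2.66e-20 for cholesterol synthesis, 2.80e-12 for immediate early genes and 1.88e-06 for p53 targets. With an estimated correlation the 5 values lay between 5.73e-06 and 0.00852. The integrated stress response had 19 of 26 members higher and 5 lower, adjusted over the list alone too, with Chac1 at 2.37 ± 0.11, and its camera adjusted p of 1.48e-06 was lost at adjusted p = 0.0553 with an estimated correlation.

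Cell cycle and growth lists fell with the addition of NAC. All 22 mitosis genes and 21 of 22 replication genes were lower, with medians of -0.68 and -0.85, and Mki67 fell from 747 ± 15.5 to 320 ± 22.8 CPM (-1.23 ± 0.04). Kif20a (-1.29 ± 0.04), the cyclin Ccnb1 (-0.99 ± 0.03), Tyms (-1.66 ± 0.05) and Rrm2 (-1.25 ± 0.03) were further examples. Ribosome biogenesis fell in 19 of 21 members and rose in 1. Mitochondrially encoded respiratory genes fell in 11 of 13 cases, with mt-Cytb at -1.34 ± 0.04. These counts held adjusted over the list alone. Camera gave adjusted p = 2.70e-17 for mitosis, 1.53e-19 for replication, 2.22e-08 for ribosome biogenesis and 7.48e-05 for the mitochondrial genes, of which the last was lost at adjusted p = 0.102 with an estimated correlation. Nuclear genes of oxidative phosphorylation had 19 of 30 members lower (20 adjusted over the list alone) and 7 higher, with a camera adjusted p of 0.0422 that was lost at adjusted p = 0.257 with an estimated correlation. That call also ended without genipin replicate 2 (0.0503), genipin replicate 3 (0.0508) or genipin+NAC replicate 1 (0.0541).

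T cell lists changed in both directions. Tcf7 (3.45 ± 0.10), Ccr7 (2.44 ± 0.05) and S1pr1 (1.42 ± 0.06) rose, and the naive and memory list was higher in 12 of 19 members and lower in 6. Tnfrsf9 (2.20 ± 0.03), Ctla4 (2.22 ± 0.04) and Pdcd1 (1.08 ± 0.03) rose within the exhaustion list, in which 10 of 18 members rose and 3 fell. Effector genes fell in 18 of 26 cases and rose in 2, with Gzmf at -1.80 ± 0.03, and interferon-response genes fell in 18 of 22 and rose in 1, with Rtp4 at -2.13 ± 0.06. The counts were unchanged adjusted over the list alone, and camera gave adjusted p = 0.00366, 2.68e-05, 5.07e-10 and 2.24e-06 for the 4 lists, or 0.0251, 0.00967, 0.000993 and 0.00620 with an estimated correlation. The macrophage list had Itgam (3.09 ± 0.09) and Cd68 (2.69 ± 0.08) higher and 2 members lower (camera adjusted p = 0.00208, or 0.0251 with an estimated correlation). The class II gene H2-Ab1 went from 5.17 ± 0.490 to 59.3 ± 4.88 CPM (3.52 ± 0.08).

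edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 9446 genes in this comparison, 4769 higher and 4677 lower, and 1995 changed at least 2-fold, 1438 higher and 557 lower. Of the calls made without normalization factors, 4539 were higher and 4922 lower. Camera called 15 lists up and 11 down, and 22 were kept with an estimated correlation. Markers of CD4 and regulatory T cells were called up but lost at adjusted p = 0.0879 with an estimated correlation. The small list of neutrophil and mast cell markers was called up (adjusted p = 0.00236, or 0.0251 with an estimated correlation) although its mean was -0.18 and its median 0.25, and in it Kit rose (2.80 ± 0.04) and the basophil protease Mcpt8 fell (-3.58 ± 0.15).

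**Figure D4:**
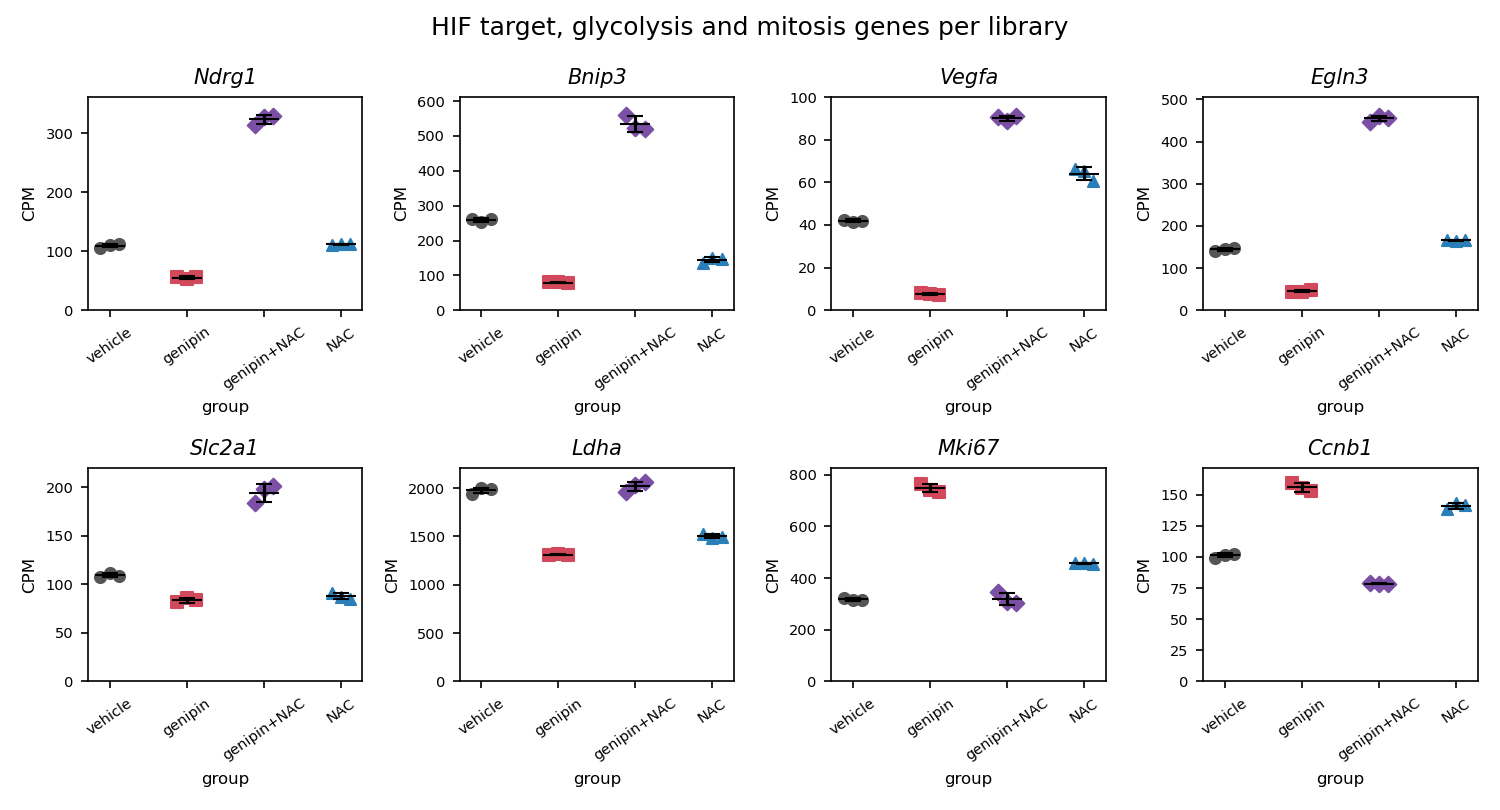
CPM (y axis, from 0) of 8 HIF target, glycolysis and mitosis genes in each library of the 4 groups (x axis), with the mean and SD of 3 libraries as black bars. Egln3 averaged 144 CPM with vehicle, 45.4 with genipin, 455 with both compounds and 165 with NAC, while Mki67 was highest with genipin at 747 CPM.

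Both compounds against NAC asks what genipin changed when NAC was present, from libraries that the comparison of genipin with vehicle does not use. Here genipin went with higher transcripts of the HIF, glycolysis, effector and exhaustion lists and with lower cell cycle transcripts. The chemokine receptor Cxcr6 (ENSMUSG00000048521.8, chromosome 9, 123806475 to 123811760) rose from 44.0 ± 1.13 to 347 ± 24.4 CPM (2.98 ± 0.05). Egr3 (2.97 ± 0.10), the semaphorin Sema6d (2.80 ± 0.12), the tight junction protein Tjp1 (2.76 ± 0.06) and the low-affinity Fc receptor Fcgr3 (2.66 ± 0.15) rose, and the cytokine Il24 (-2.59 ± 0.06), Itgae (-2.16 ± 0.13), the tubulin Tubb2b (-1.92 ± 0.15), Zbtb18 (-1.87 ± 0.12) and Igfbp4 (-1.84 ± 0.09) fell.

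Of 17 HIF targets 15 rose and 1 fell, with a median of 1.053 and Bnip3 at 1.88 ± 0.04, and of 19 glycolysis genes 17 rose (18 adjusted over the list alone) and 1 fell, with Slc16a3 at 1.76 ± 0.04. The effector list rose in 19 of 26 members and fell in 3, with Gzmd (2.10 ± 0.03), Gzme (2.08 ± 0.03) and Gzmg (2.14 ± 0.03) in the lead. In the exhaustion list 14 of 18 rose and 3 fell, with Pdcd1 at 2.51 ± 0.04 and Havcr2 at 1.602 ± 0.04. Cytokines and chemokines rose in 11 of 15 cases and fell in 2, with Ccl5 at 2.48 ± 0.04 and Spp1 at 1.86 ± 0.04. Natural killer markers rose in 6 of 6 cases, with Fcer1g at 1.21 ± 0.08. The other counts were the same adjusted over the list alone. Camera gave adjusted p = 8.51e-45, 6.01e-26, 4.60e-38, 8.71e-15, 2.75e-08 and 0.000191 for these 6 lists in that order, and all held with an estimated correlation, at adjusted p between 1.22e-05 and 0.00954. Of 13 macrophage and monocyte markers 4 were tested, and all 4 rose (median 1.85, camera adjusted p = 2.55e-05, or 0.00548 with an estimated correlation). Of 12 neutrophil and mast cell markers 3 were tested, and all 3 rose (median 1.98, camera adjusted p = 7.80e-14, or 0.000351 with an estimated correlation). Untested members of these 2 lists had at most 7 (Lyz2) and 15 (Ltf) counts in any library. B cell markers fell in 4 of 5 cases and rose in 1, and dendritic cell markers fell in 3 of 5 and rose in 1. Neither list was called (camera adjusted p = 0.225 and 0.780).

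All 22 mitosis genes fell, with a median of -0.72 and Cdc20 at -0.98 ± 0.04, and 20 of 22 replication genes fell, with Mcm2, a helicase subunit, at -0.83 ± 0.03. The integrated stress response fell in 25 of 26 members and rose in 1, with the amino acid transporter Slc7a5 at -1.10 ± 0.04. Cholesterol synthesis fell in 20 of 23 and rose in 1, with Acat2 at -1.02 ± 0.03, and fatty acid synthesis fell in 11 of 13 and rose in 1 (2 adjusted over the list alone), with Fasn at -0.99 ± 0.04. Ribosome biogenesis fell in 16 of 21 (17 adjusted over the list alone) and rose in 1, with Gnl3 at -1.15 ± 0.05. The remaining counts were the same adjusted over the list alone. Adjusted p by camera was 7.24e-30 for mitosis, 3.43e-14 for replication, 1.74e-24 for the stress response, 2.08e-11 for cholesterol synthesis, 1.04e-05 for fatty acid synthesis and 3.35e-14 for ribosome biogenesis. With an estimated correlation these lay between 9.76e-05 and 0.00346.

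The quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment called 7239 genes, 3632 higher and 3607 lower, and 805 changed at least 2-fold, 468 higher and 337 lower. Without normalization factors the split was 2650 higher and 4733 lower. Camera called 14 lists up and 12 down, and 23 were kept with an estimated correlation. The p53 targets fell in 11 of 20 cases and rose in 3, adjusted over the list alone too (camera adjusted p = 0.0447), a call lost at adjusted p = 0.0741 with an estimated correlation and at 0.0540 without genipin+NAC replicate 1. Mitochondrially encoded respiratory genes rose in 10 of 13 cases, adjusted over the list alone too (camera adjusted p = 0.0361), a call lost at adjusted p = 0.427 with an estimated correlation and at 0.0508 without the same replicate. The unfolded protein response list fell in 11 of 18 cases (12 adjusted over the list alone) and rose in 2, with adjusted p = 0.0120 by camera and adjusted p = 0.119 with an estimated correlation.

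The interaction asks whether the genipin effect differed with NAC present, and it is the genipin change with NAC minus the genipin change without it. The HIF, glycolysis and cell cycle lists went in opposite directions under the 2 conditions. The HIF median was -0.998 for genipin without NAC and 1.053 with it, and all 17 targets had a higher genipin effect with NAC, by a median of 1.87, with Bnip3 at 3.59 ± 0.05 and Egln3 at 3.13 ± 0.05. Glycolysis differed by a median of 1.12, higher in 18 of 19 genes and lower in 1, with Slc16a3 at 2.68 ± 0.06 and Pgk1 at 2.20 ± 0.03. All 22 mitosis genes and all 22 replication genes had a lower genipin effect with NAC, by medians of -1.34 and -1.03, with Kif20a at -1.85 ± 0.05 and Rrm2 at -1.40 ± 0.04. Immediate early genes differed upward in 15 of 16 cases, by a median of 1.301, with Egr1 at 1.90 ± 0.04. Cholesterol synthesis differed upward in 19 of 23 and downward in 1, with Fdps at 1.43 ± 0.04, and the effector list in 20 of 26 and 3, with Gzmg at 2.35 ± 0.05. These counts were the same adjusted over the list alone. Camera gave adjusted p = 6.94e-84 for HIF targets, 6.72e-70 for glycolysis, 6.73e-63 for mitosis, 1.48e-30 for replication, 2.02e-27 for immediate early genes, 7.64e-20 for cholesterol synthesis and 3.23e-18 for effector genes. With an estimated correlation they lay between 1.01e-06 and 0.00116.

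Single genes with a large interaction included Tgm2 (5.99 ± 0.31) and Nos2 (4.97 ± 0.20) upward, and Itgae (-6.09 ± 0.21), Asb2 (-3.81 ± 0.15) and the prostaglandin D synthase Hpgds (-2.92 ± 0.17) downward. The size for Tgm2 is uncertain, because its mean with genipin lay below the level of 3 counts per library. Itgae illustrates the design: it averaged 0.778 CPM with vehicle, 11.99 with genipin, 9.74 with NAC and 2.19 with both. The interaction test called 7008 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3733 upward and 3275 downward, and 1345 differed at least 2-fold, 917 upward and 428 downward. Without normalization factors the split was 2618 upward and 4806 downward. Of 40 lists 12 were called up and 4 down by camera, 15 of them kept with an estimated correlation, the lost one being other antioxidant enzymes (adjusted p = 0.257 with an estimated correlation). The integrated stress response was not called in the interaction (camera adjusted p = 0.903, median -0.09, mean 0.44), having fallen with genipin both without and with NAC. Its members differed in both directions, 10 of 26 upward and 9 downward (10 downward adjusted over the list alone).

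**Figure D5:**
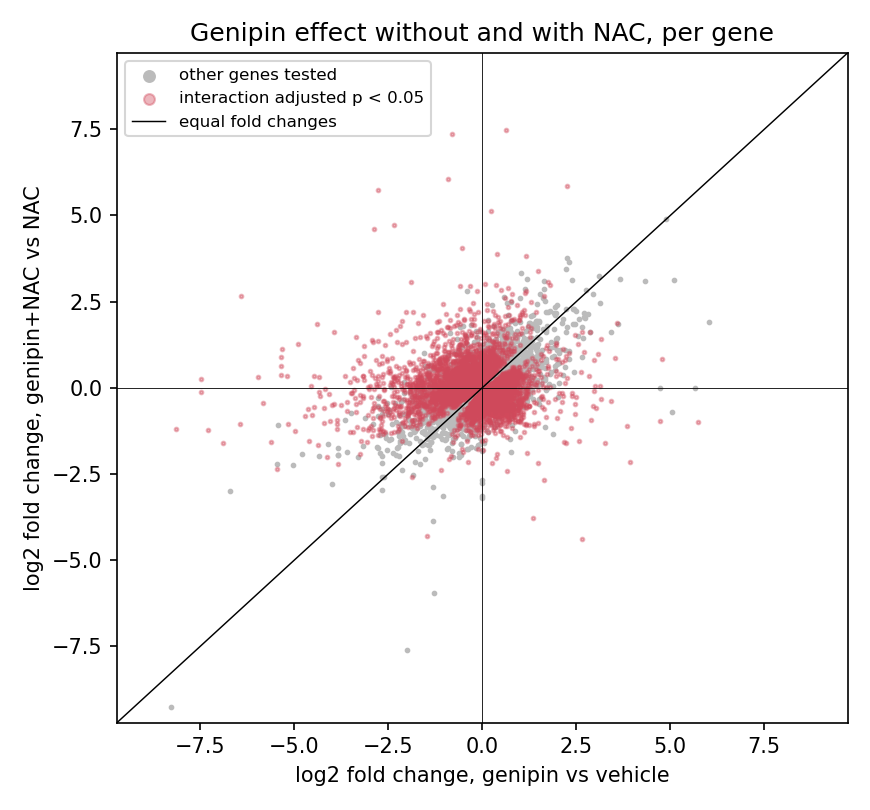
Log2 fold change of each of 13636 genes for genipin against vehicle (x axis) and for both compounds against NAC (y axis), with genes past the interaction test in red, others in grey and the line of equal fold changes in black. The 7008 red points lie off the line, and Pearson's r over all genes was 0.294.

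The genipin effects without and with NAC come from separate libraries and were compared across genes, which are not independent replicates. Pearson's r was 0.294 and Spearman's rho 0.236 over 13636 genes, and the slope among genes called without NAC was 0.217. Both effects were called higher for 1599 genes and lower for 1617, against 1087 and 1120 expected from independent calls. In opposite directions 1850 genes were called, against 2207 expected. The NAC effects without and with genipin were closer, with r = 0.570, rho = 0.478 and a slope of 0.729. They shared 2466 higher and 2431 lower genes, against 1413 and 1404 expected from independent calls, with 1458 in opposite directions against 2818. The expected numbers take the calls of 2 contrasts as independent, so genes prone to be called in both can inflate the excess of shared calls. Simulated data without group differences gave r = 0.0147 and 0.00526 for these 2 relations.

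Of the 424 genes that genipin raised at least 2-fold against vehicle, 287 (67.7%) fell when NAC was added to genipin, and 178 were still above vehicle with both compounds. Of the 912 genes that it lowered at least 2-fold, 777 (85.2%) rose when NAC was added, and with both compounds 268 were still below vehicle, 352 were not called and 292 were above it. The median of the lowered genes was -1.60 with genipin and 0.07 with both compounds, each against vehicle. These genes were picked on libraries that both contrasts use, so part of the return arises from the selection. Compared with NAC alone, in libraries not used to pick the genes, both compounds had 187 of the raised genes higher and 40 lower, and 395 of the lowered genes lower and 121 higher. Across all genes, genipin against vehicle and both compounds against genipin had r = -0.716, where simulated data without group differences gave -0.495 from the shared libraries alone, and a covariance of -0.511 against a simulated -0.0199. Genipin against vehicle and NAC against vehicle had r = -0.112 (simulated 0.498) and a covariance of -0.0644 (simulated 0.0202). Genipin against vehicle and both compounds against vehicle had r = 0.127 (simulated 0.510) and a covariance of 0.0636 (simulated 0.0207). The 3 libraries of a group are too few to split. Part of the excess in the first pair may come from the shared genipin libraries, a small part by the simulated covariance. In the 2 pairs that share vehicle libraries r lay below the simulated value, which holds for libraries without group differences. The covariance of genipin and both compounds, each against vehicle, lay above the simulated one, and that of genipin and NAC was negative.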

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

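The tests of B cells by Igkc and Cd74, of dendritic cells or macrophages by Cd74 and H2-Aa, and of poly(A) enrichment were chosen only after the result was seen. The results of this part stand out because the genipin effect differed between cells without and with NAC by the interaction test, which called 7008 genes. Of the 60 regroupings drawn, the real one called 7008 genes and the highest other 289, so 1 of 60 had as many. The other regroupings mixed libraries of different groups, which widens the spread within each. They ask whether the groups differ at all and cannot decide on an interaction by themselves. For the 5 contrasts of 3 against 3 libraries, fits on 6 libraries called 8638 genes for genipin against vehicle, 8493 for NAC against vehicle, 7395 for both against vehicle, 9136 for both against genipin and 6757 for both against NAC. The highest other split called 0 genes each time, the real split was the 1 with as many genes, and 10 splits are too few for a share under 0.05.

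Among single genes, the interaction was 5.99 for Tgm2 (-5.36 without NAC, 0.63 with it) and 4.97 for Nos2 (-2.76 and 2.21). It was 4.36 for Mgarp (-3.15 and 1.20) and 4.26 for Plcxd1 (-2.92 and 1.34). Downward it was -6.09 for Itgae (3.93 and -2.16), -3.81 for Asb2 (3.43 and -0.37), -2.92 for Hpgds (2.46 and -0.46), -2.16 for Serpina3g (2.98 and 0.82) and -1.96 for Plk1 (1.00 and -0.97). The values of Tgm2 without NAC and for the interaction are uncertain in size, because its genipin mean lay below 3 counts per library.

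Lists with a median genipin effect that differed upward with NAC, by camera, were HIF targets (1.87; -0.998 without NAC and 1.053 with it), glycolysis (1.12), immediate early genes (1.301), macrophage and monocyte markers (1.52) and cholesterol synthesis (0.74). Smaller upward differences were those of effector genes (0.45), cytokine and chemokine receptors (0.34), p53 targets (0.32), other antioxidant enzymes (0.26), inhibitory receptors and exhaustion (0.24), fatty acid synthesis (0.22) and NF-kB targets (0.21). The call of other antioxidant enzymes was lost at adjusted p = 0.257 with an estimated correlation. Mitosis (-1.34), DNA replication (-1.03), the unfolded protein response (-0.44) and ribosome biogenesis (-0.39) differed downward.

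HIF targets were lower with genipin than with vehicle and higher with both compounds than with genipin. A bias from GC content or transcript length is argued against, since removing a smooth trend on both left a median of -1.01 in the first contrast (spread 0.475) and 2.42 in place of 2.55 in the second. The 3 scalings moved the first median by 6.51% of its size, so it depended little on the choice among them. TMM factors differed little between these groups (0.961 to 0.963 with vehicle, 1.00 to 1.01 with genipin), so a large shift was not possible. All 3 scalings are relative, so a change in total RNA per cell was not tested. A fall of all metabolic transcripts alike is argued against by a gap of 0.87 to the nearer of the TCA cycle (-0.13) and nuclear oxidative phosphorylation (-0.09) medians. Cholesterol synthesis (-1.13), glycolysis (-0.59) and fatty acid synthesis (-0.56) fell along with the HIF targets, so a fall shared with these lists stays open. The compounds themselves remain as a hypothesis, and oxygen, cell density and glucose in the cultures were not measured and may also have differed.

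Ighm and class II genes differed between groups, which could come from other cells in the cultures. The summed B cell genes rose by 1.89 with NAC against vehicle, so the prediction written beforehand for B cells was met, through Cd79b (2.65 to 9.79 CPM), while Cd79a, Ms4a1 and Pax5 had 0 CPM with vehicle and at most 0.199 CPM with NAC. Igkc and Cd74, abundant in B cells, changed by 0.0149 in sum (3.89 to 3.94 CPM) while Ighm went from 39.3 to 188 CPM, and the verdict against B cells rests on this test, chosen later. Dendritic cell and macrophage genes changed by 0.95 in sum with both compounds against genipin (1.04 to 2.04 CPM), which met neither bound set beforehand, and Cd74 and H2-Aa changed by -0.51 (2.25 to 1.602 CPM) while H2-Ab1 went from 5.17 to 59.3 CPM. Of the summed genes Zbtb46 rose most (0.71 to 1.82 CPM), while Lyz2, Csf1r, Adgre1 and C1qa to C1qc had means of at most 0.0681 CPM in both groups. Of 13 macrophage and monocyte markers 4 were tested there, 2 higher (Itgam at 3.09 and Cd68 at 2.69) and 2 lower. That list was called up, which goes with such cells, so the verdict against them rests on Cd74 and H2-Aa, both at low levels. Cd74 fell (2.10 to 1.37 CPM) while H2-Aa rose (0.150 to 0.233 CPM). By edgeR's quasi-likelihood test the Cd74 call was lost without genipin replicate 3 (adjusted p = 0.109) or genipin+NAC replicate 3 (adjusted p = 0.0908). Expression of Ighm and H2-Ab1 transcripts by the T cells themselves remains a hypothesis.

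Transcripts without a poly(A) tail took very little of the counts, although the labels describe total RNA. The highest TPM of Rn7sk, Rpph1, Rmrp and Terc in any library was 105 (Rn7sk), with 50.7, 9.59 and 0.42 for the others, which met neither bound, so enrichment for poly(A) RNA stays open and may explain it. A loss of short transcripts is argued against: 14 ribosomal protein genes of 400 to 700 bases had a median of 892 CPM, while 67 replication-dependent histone genes had 0.197 CPM. No biological explanation was tested.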

How the results depend on the processing

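The glmTreat test was chosen after the result was seen. Over the alternatives, the 981 results of named genes kept direction and side of the threshold in 21239 cases and lost the threshold in 75, and none reversed. The 129 list calls were kept in 1907 cases and lost in 28. An estimated correlation kept 108 of the 129 and lost 21, and leaving out a library kept 1541 cases and lost 7. The fry test kept all 129, but it called 33 to 39 of the 40 lists in each contrast, so it could hardly lose any. Counts of called genes stayed within 1.5 times under the other scalings, tests and filters and under the replicate block, which gave 8246, 8050, 7768, 9373, 7152 and 6958 in the order of the contrasts in the report and changed no list call. A change of at least 2-fold gave 1336, 1352, 1083, 1995, 805 and 1345 genes, and glmTreat against 1.5-fold gave 1473, 1423, 1105, 2589, 832 and 1431, both lower by construction. With 1 library left out, the counts ranged from 7724 to 8695, 7494 to 8541, 7162 to 7807, 8914 to 9463, 6528 to 7222 and 6641 to 7237.

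The correlation of the genipin effects without and with NAC, 0.294, was 0.235 with the filter at 5 CPM and ranged from 0.270 to 0.298 with 1 library left out. That of the NAC effects, 0.570, was 0.527 with the filter and ranged from 0.543 to 0.561. The filter tests fewer genes, and for the rest the cause was not tested. The replicate block gave 0.293 and 0.569.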

Other observations

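No test in this part was chosen after the result was seen. Several lists outside the main account changed with genipin against vehicle (log2 fold changes ± SE, n = 3 per group). Of 19 genes of the TCA cycle 13 fell and none rose, 14 falling when adjusted over the list alone, with the NADP-dependent isocitrate dehydrogenases Idh1 at -1.25 ± 0.08 and Idh2 at -1.06 ± 0.08 (camera adjusted p = 0.0121, or 0.0441 with an estimated correlation). Of 17 genes of amino acid and polyamine metabolism 13 fell and 1 rose, the same adjusted over the list alone, with the adenosylhomocysteinase Ahcy at -0.46 ± 0.03 (camera adjusted p = 0.00186, or 0.0272 with an estimated correlation). That list also lay below NAC alone with both compounds, in 12 of 17 genes with 3 above (camera adjusted p = 3.65e-06, or 0.00248 with an estimated correlation).

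Iron and death regulators moved without a net call in genipin against vehicle. The transferrin receptor Tfrc rose (0.64 ± 0.03) and the ferritin heavy chain Fth1 fell (-0.71 ± 0.04), with 3 of 11 iron genes higher and 7 lower (camera adjusted p = 0.248). The proapoptotic Bcl2l11 rose (1.11 ± 0.05) in a list with 10 of 16 members higher and 5 lower (camera adjusted p = 0.149). With NAC against vehicle, 9 of 16 fatty acid oxidation genes fell (11 adjusted over the list alone) and 2 rose (camera adjusted p = 0.00670, or 0.0431 with an estimated correlation).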
